A study of Mus musculus with 6 samples.

How the data were processed

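Tumor RNA from 6 mice, 3 with a duodenal and 3 with a cecal tumor, was hybridised to 1 Affymetrix expression array each. The values used are linear probe set intensities, made by the authors with MAS5 per the submitters' processing notes. Its version, scaling target and detection calls are not given in the sources used here. The deposited intensities had a mean of 500 to 500.8 per array between the 2nd and 98th percentiles, so the arrays had been scaled to a common level by the authors. No background correction, scaling or normalization between arrays was added. Groups and replicate numbers come from the sample titles, and the labels' protocols state that the tumors came from different mice.

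Probe sets were named through the platform annotation and checked against a RefSeq gene table of assembly GRCm38.p6, which was used for names and chromosomes only. Of 22690 probe sets, 20380 named exactly 1 gene, 691 named several, 1555 had no name in the table and 64 were controls, which were left out. Gene ids of 20364 probe sets were found in the RefSeq table and 0 symbols changed. Probe sets with several names or none entered the probe set count and named no gene. No coordinates are given, since the sources used here name no build for the array.

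A probe set was tested when its intensity was above its array's 40th percentile (92.4 to 100.6) on at least 3 of the 6 arrays. Values were transformed as log2(intensity + 16), which understates the change of dim genes, and compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Folds are cecal minus duodenal. A gene was represented by its brightest probe set on average. Where a probe set was below the 40th percentile on all 3 arrays of one group, which stands in here for detection calls, the fold is given as at least the bright group's mean log2 intensity over the dim group's percentile level. Such a probe set was tested only if above that level on all 3 arrays of the other group. The direction of its fold thus largely follows from the filter. Means are given with the SD over 3 tumors, and log2 folds with the limma standard error.

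Before the data were examined, 39 gene lists, the test, the filter, the alternatives and the rule for naming genes were fixed. The rule takes Rb1 and Apc, the 12 largest rises and 12 largest falls by fitted log2 fold that passed with no overlap between groups, up to 4 members of each list with the smallest p, and up to 3 brightest members of each list of other cell types or sample handling. Of 671 list entries 573 were on the array. The 32 lists with at least 4 tested members, the sex-linked list excepted, were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. Other tested probe sets existed for 62 of 202 named genes, 86 in all; 2 had the opposite sign of the gene's representative and 13 lay on the other side of the threshold, but none was opposite with both past it.

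Replicate numbers 1 to 3 recur in both groups. Deviations from the group means correlated at 0.274, 0.299 and 0.203 between tumors of the same number, and at -0.2 to -0.026 between tumors of different numbers. The deviations of a site's tumors cancel out, which pulls the latter values down. As each same-number correlation was over 0.1, the numbers were treated as pairing the samples. This pairing comes from the data alone, since the labels name no shared litter, day or batch. Chance is not excluded as its source, and every value with the block rests on this pairing. The main test has no block, as fixed beforehand, and a fit with the replicate number as a block was run as an alternative.

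Alternatives covered the offset, the filter, quantile normalization, median centring, the variance model, array weights, probe set choice, the list test, stricter thresholds and leaving out each array. The 4 arrays of male mice alone, and the gene count without the stomach list, were added after the data were seen. The procedure was tested on simulated data with the means and spreads of the 13866 real probe sets, 200 of them changed. In the simulation it called 62% of 100 probe sets changed 2-fold and 88% of 100 changed 4-fold, 0 with the wrong sign, and 5.06% of its calls were unchanged probe sets. The simulated noise was drawn independently for each array and so leaves out the deviations shared by tumors of the same number, which that share does not cover. The 200 changed probe sets were a smaller share than the 9.3% called in the real data, so the 62% and 88% need not hold there. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.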

Results

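The data set held 6 microarrays of mouse intestinal tumors, 3 from the cecum and 3 from the duodenum, each from a different mouse. The mice carried Apc1638N, an allele of the Apc tumor suppressor gene that predisposes to intestinal tumors, and were deficient in Rb1, the retinoblastoma tumor suppressor. Per the labels, the duodenal samples could include tumor tissue that arose at the pylorus, the outlet of the stomach. Each array gave an intensity for 22690 probe sets, and 13866 probe sets, covering 8129 genes, were bright enough to be tested. The arrays' median intensities ranged from 164.6 to 181.8, and the number of arrays limits the precision of every value. The comparison asked how tumors of the 2 sites differ in gene expression. No normal tissue and no tumor with intact Rb1 was analysed here, so each difference is one between tumors of the 2 sites, which also differ as normal tissues.

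Rb1 was measured by 1 probe set, with an intensity of 331.2 ± 26.2 (SD, n = 3) in duodenal and 360.4 ± 25.1 (n = 3) in cecal tumors. The arrays ranged from 306.7 to 387.5, and the difference was within the replicate spread (limma adjusted p = 0.663). Apc gave 844.9 ± 58.8 in duodenal and 765.6 ± 130.7 in cecal tumors (adjusted p = 0.62). A second tested Apc probe set had a log2 fold of -0.495 and did not pass (limma adjusted p = 0.27), though its values did not overlap between the sites. Another Apc probe set was too dim to be tested. Which part of either transcript the probe sets cover relative to the engineered change was not determined here, so these values check neither label.

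Tumors of the 2 sites differed in 850 of the 8129 genes. In cecal tumors 464 genes were higher and 386 lower, of which 255 and 231 differed at least 2-fold. The balance turned without duodenal tumor 2 (383 higher, 412 lower) and with the male arrays alone (221 higher, 269 lower). Genes that passed without overlap between the groups were ranked by fitted log2 fold, an order that is not settled where a group was dim. The 12 ranked first among the rises in cecal tumors were Car1, a carbonic anhydrase of the colon surface, 2610528A11Rik, 1810065E05Rik, Saa1, an acute-phase serum amyloid, Hao2, Prss30, Cyp2c55, Retnlb, a goblet cell product, Tmigd1, Aqp8, Slc13a2 and the membrane mucin Muc3. The 12 ranked first among the falls were Gkn2, Tff2, Gkn1, Psca, Anxa10, 2310057J18Rik, Muc1, the fatty acid binding protein Fabp1, Cldn18, Muc5ac, the calcium binding protein S100g and Reg1. Car1 had an intensity of 18.2 ± 12.3 in duodenal and 11196 ± 456 in cecal tumors, at least 111-fold higher in cecal tumors (adjusted p = 1.42e-06). Gkn2 had 13512 ± 2640 in duodenal and 46.2 ± 43.6 in cecal tumors, at least 139-fold higher in duodenal tumors (adjusted p = 8e-05).

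By probe set, 1290 of 13866 passed the same limma test, 726 higher and 564 lower in cecal tumors. The values of the 2 groups did not overlap for 31.2% of the genes. Chance gives 10% for independent arrays, a value that leaves out the pairing by replicate number. The first principal component held 63.2% of the variance and separated the sites, and correlations between arrays were 0.9505 to 0.9715 within a site and 0.8659 to 0.9107 between sites. The count of genes fell to 446 without cecal tumor 1, to 478 without cecal tumor 2 and to 554 without duodenal tumor 1. Among these 24 ranked genes, the call of Retnlb was lost without cecal tumor 1 (adjusted p = 0.0731).

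**Figure D1:**
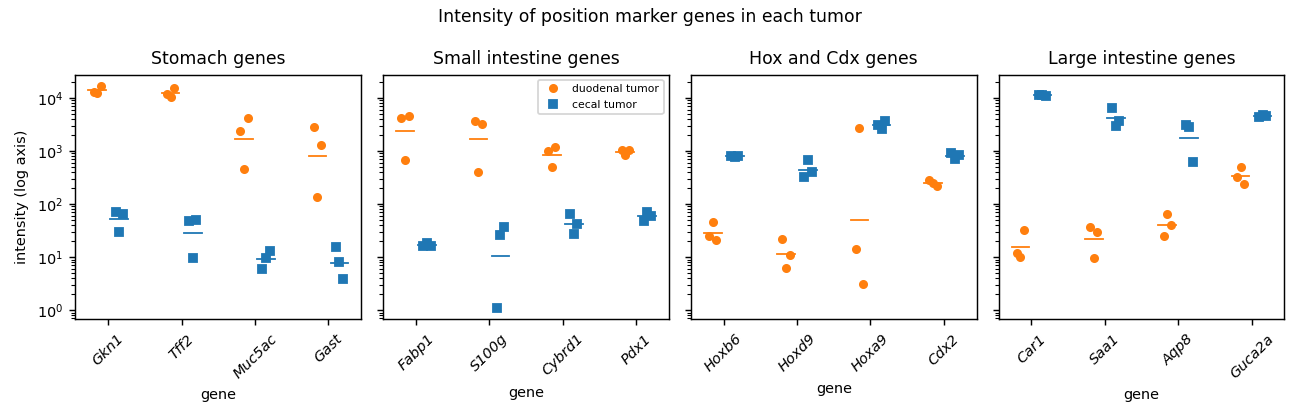
Intensity (log axis) of 16 genes in each of the 3 duodenal tumors (circles) and 3 cecal tumors (squares), with a horizontal line at each group's geometric mean. Gkn1 lies between 12496 and 17057 in duodenal tumors and at or below 71.8 in cecal tumors, and Hoxa9 is high in duodenal tumor 2 alone among the duodenal tumors.

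Genes of the stomach and pylorus were far higher in duodenal tumors. Of 14 tested members of that list, 13 were lower in cecal tumors and none was higher, or 14 lower adjusted over the list alone. For 11 of the 14, dim in all tumors of 1 site, the direction of the fold largely follows from the filter. Gkn1, a secreted protein of the gastric surface, fell from 14090 ± 2573 to 55.1 ± 22.7 (SD, n = 3 each), at least 145-fold higher in duodenal tumors. Tff2, a trefoil peptide of gastric mucous cells, was at least 128-fold higher and Anxa10 at least 82-fold higher. Tff1 fell by 4.38 ± 0.17 (SE) on the log2 scale (adjusted p = 5e-06), and Ctse by 3.67 (adjusted p = 0.000281). A second Ctse probe set had a log2 fold of -0.73 and did not pass (adjusted p = 0.534). The list's median log2 fold was -5.57, or -4.25 with genes dim in a whole group at their bound (camera adjusted p = 1.29e-19). With an estimated correlation the adjusted p was 0.233. Duodenal tumors also held the antral hormone gene Gast at 2805, 134.6 and 1319.9 in tumors 1, 2 and 3. Among genes of the acid-secreting stomach body in duodenal tumors, Atp4b stayed at or below 42.6, Atp4a reached 135.7 in tumor 2, and Cblif 256.1 and 364.5 in tumors 1 and 3.

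Genes of gut position separated the sites in both directions. The array held 21 distal position genes, of which 10 were tested. Of these 10, 8 were higher in cecal tumors and none was lower, or 9 higher and 1 lower adjusted over the list alone. For 5 of the 10, dim in all tumors of 1 site, the direction of the fold largely follows from the filter. Hoxb6 rose from 30.4 ± 13.3 to 803 ± 17.9, at least 8-fold, and Hoxd9 at least 4.43-fold. Cdx2, an intestinal homeobox factor, rose from 252.8 ± 33.7 to 819.2 ± 116.4 (log2 fold 1.63 ± 0.16 SE, adjusted p = 0.000783). The list's median was 3.19, or 1.98 with bounds (camera adjusted p = 8.72e-09; adjusted p = 0.198 with an estimated correlation). Hoxa9 did not pass (log2 fold 4.73 ± 1.61 SE, adjusted p = 0.117), since duodenal tumor 2 had 2768.4 where the other duodenal tumors had 14.2 and 3.1. Its adjusted p was 1.04e-05 without that tumor, 3.63e-05 with the male arrays alone, which also leave it out, and 0.0241 with array weights.

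Of 9 tested proximal gut transcription factors, 5 fell and 1 rose in cecal tumors, also adjusted over the list alone. The lowest log2 fold, -3.82, was that of Sox2, named after its values were seen. It had 733.8, 301 and 799.8 in duodenal and 6.6, 46.1 and 33.1 in cecal tumors. Sox2 is also on the stomach and pylorus list, so the 2 lists are not independent. Pdx1, a factor of the duodenum and pancreas, fell from 974.9 ± 112.4 to 59.6 ± 11.6, at least 10.1-fold higher in duodenal tumors (adjusted p = 1.26e-05). Gata5 fell by 2.44 ± 0.23 (SE) on the log2 scale, and Gata4 was at least 4.19-fold higher in duodenal tumors. The member that rose was Nr1h4, the bile acid receptor FXR (log2 fold 2.27 ± 0.27 SE). The median was -1.04 (camera adjusted p = 0.022; adjusted p = 0.465 with an estimated correlation). The call was lost without duodenal tumor 3 (adjusted p = 0.0508), without cecal tumor 3 (adjusted p = 0.0555) and with the mean of each gene's probe sets (adjusted p = 0.058).

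Genes of the large intestine epithelium were higher in cecal tumors. Of 14 tested members, 11 rose and 2 fell, also adjusted over the list alone. For 6 of the 14, dim in all tumors of 1 site, the direction of the fold largely follows from the filter. Guca2a, which encodes the hormone guanylin, rose from 355.3 ± 137.6 to 4564 ± 240 (log2 fold 3.69 ± 0.24 SE, adjusted p = 0.000113), Saa1 was at least 41.4-fold higher and Cyp2c55 at least 31-fold higher. The members that fell were Sult1c2 (log2 fold -2.97) and Ggh (log2 fold -1.29), both named after their values were seen. The call of Ggh (adjusted p = 0.0482) was lost with the block (0.0585), quantile normalization (0.0538), median centring (0.0573), no filter on dim probe sets (0.0746) and no intensity trend (0.0609). It was also lost with the mean of its probe sets (0.0501), with the male arrays alone (0.0758) and without any single array but duodenal tumor 2 (0.066 to 0.117). The median was 3.49, or 2.83 with bounds (camera adjusted p = 1.26e-08; adjusted p = 0.375 with an estimated correlation).

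No list of small intestinal absorption genes passed. In the lipid absorption list, 2 of 14 tested members fell and 1 rose, or 5 and 3 adjusted over the list alone and 3 and 2 with the replicate number as a block. Fabp1 was at least 24.7-fold and Mttp, which loads lipid onto lipoproteins, at least 5.16-fold higher in duodenal tumors, while Dgat2 rose by 0.89 ± 0.16 (SE), a call lost with the male arrays alone (adjusted p = 0.0766). The list's median was -0.41 (camera adjusted p = 0.18), and it passed without duodenal tumor 2 (adjusted p = 0.0102), with the male arrays alone (0.00651) and with no filter on dim probe sets (0.0121). Of 7 brush border hydrolases, 3 rose and 1 fell (4 and 1 adjusted over the list alone). The meprin Mep1a rose (log2 fold 3.91 ± 0.32 SE), and the peptidase Dpp4 was at least 2.62-fold higher in cecal tumors. Mep1b, which also rose (limma adjusted p = 0.0307), is on the large intestine epithelium list too. Its call was lost without duodenal tumor 3 (0.0754), cecal tumor 1 (0.12) or cecal tumor 2 (0.0997) and with the male arrays alone (0.106). The hydrolase list's camera adjusted p was 0.118, or 0.0482 without duodenal tumor 1. Of 7 sugar, peptide and amino acid transporters, 2 rose and 2 fell (2 and 3 adjusted over the list alone; list adjusted p = 0.754), with Slc7a9 lower in cecal tumors by a log2 fold of -2.28 ± 0.27 (SE). Of 8 iron and calcium uptake genes, 3 fell and 1 rose, also adjusted over the list alone (list adjusted p = 0.609). Cybrd1, a duodenal iron reductase, was at least 8.63-fold and S100g at least 17.5-fold higher in duodenal tumors, while Heph rose by 0.88 ± 0.14 (SE).

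Markers of epithelial cell types moved in both directions. Of 15 goblet cell genes, 6 rose and 1 fell in cecal tumors, or 7 and 2 adjusted over the list alone. Retnlb and Guca2a, among those that rose, are also on the large intestine epithelium list, so the 2 lists share these rises. Spink4 rose by 1.91 ± 0.20 (SE) and Atoh1, the secretory lineage factor, by 2.02 ± 0.27, whereas Clca1 fell by 3.12 ± 0.39 on the log2 scale. The list did not pass (camera adjusted p = 0.116; 0.0488 with the replicate number as a block). It also passed without duodenal tumor 1 (adjusted p = 0.0132), duodenal tumor 3 (0.0477) or cecal tumor 2 (0.0491). Of 10 enteroendocrine genes, 2 fell and 1 rose, also adjusted over the list alone. Neurog3, the endocrine progenitor factor, was at least 2.58-fold higher in duodenal tumors and the glucagon gene Gcg at least 2.94-fold higher in cecal tumors, a call lost without cecal tumor 1 (adjusted p = 0.0628). The enteroendocrine list's adjusted p was 0.121, or 0.0488 with the block, 0.000444 without duodenal tumor 2, 0.00105 with the male arrays alone, 0.0377 with array weights and 0.00256 with no filter on dim probe sets. Of 5 Paneth cell genes 1 rose, also adjusted over the list alone: Lyz1, by 0.69 ± 0.14 (SE), a call lost without cecal tumor 2 (adjusted p = 0.0788) and with the male arrays alone (0.129). Other Lyz1 probe sets had log2 folds of 0.93, which passed (adjusted p = 0.0121), and 0.51, which did not (adjusted p = 0.237). That list's median of -0.32 and mean of -0.05 were negative while its test pointed upward (adjusted p = 0.631). The tuft cell list had 2 tested members and was not tested; Avil fell by 2.44 ± 0.41 (SE; 2 lower adjusted over the list alone or with the block), and Dclk1 had a log2 fold of -0.90 (adjusted p = 0.114, or 0.0329 with the block, 0.0391 without duodenal tumor 2 and 0.0253 with array weights).

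Glycolysis and hypoxia genes were higher in cecal tumors by moderate amounts. Of 18 members, 9 rose and none fell, or 13 rose adjusted over the list alone or with the block. Hk2, a hexokinase, rose from 842.5 ± 187.1 to 3844 ± 880 (SD, n = 3 each; log2 fold 2.17 ± 0.21 SE, adjusted p = 0.000733). Egln3, an oxygen-sensing hydroxylase, rose by 1.01 ± 0.16 (SE) and Pfkl, a phosphofructokinase, by 0.65 ± 0.11. A second Egln3 probe set, at 0.65, did not pass (adjusted p = 0.0648), and the call of Pfkl was lost with the male arrays alone (adjusted p = 0.0774). The median was 0.54 (camera adjusted p = 1.26e-08; adjusted p = 0.421 with an estimated correlation). Among other metabolic lists, 2 of 4 bile acid genes rose (2 and 1 lower adjusted over the list alone or with the block; list adjusted p = 0.339), 4 of 19 xenobiotic genes rose and 3 fell (5 and 3 adjusted over the list alone, 4 and 5 with the block; list adjusted p = 0.609), and 2 of 15 PPAR alpha and fatty acid oxidation genes rose and 2 fell, also adjusted over the list alone (list adjusted p = 0.891). The transporter Abcg2 rose by 2.69 ± 0.32 (SE) and Gsta4, a glutathione transferase, fell by 1.59 ± 0.22. The PPAR alpha list's median was -0.03 and its mean -0.04, and its camera test pointed upward. None of 14 cholesterol synthesis genes passed, also adjusted over the list alone, and 1 rose with the block (median 0.19, list adjusted p = 0.0767; 0.0488 with the block and 0.0491 without cecal tumor 2).

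None of 33 E2F targets and proliferation genes passed, also adjusted over the list alone, and their log2 folds ran from -0.21 to 0.55 with a median of 0.11. With the block 1 rose. Pcna was at 6948 ± 1138 in duodenal and 8530 ± 2165 in cecal tumors (adjusted p = 0.485). The list's camera adjusted p was 0.177, or 0.0488 with the replicate number as a block. It also passed without duodenal tumor 1 (adjusted p = 0.0258), duodenal tumor 2 (0.0102) or cecal tumor 3 (0.00861) and with the male arrays alone (0.0381). Of 20 Rb family, E2F and cyclin-CDK regulators, 1 rose, also adjusted over the list alone, or 2 rose and 1 fell with the block (list adjusted p = 0.238). The 1 was Mdm2, the p53 ubiquitin ligase, at 491.2 ± 32 in duodenal and 1272 ± 341 in cecal tumors (log2 fold 1.31 ± 0.19 SE, adjusted p = 0.00479). A second Mdm2 probe set gave a log2 fold of 0.14 (adjusted p = 0.802), and the mean of the probe sets did not pass (adjusted p = 0.0681).

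Of 21 intestinal stem cell and Wnt target genes, 1 fell in cecal tumors, or 3 adjusted over the list alone, and 18 had a negative fold. With the replicate number as a block 9 fell. These included Notum (log2 fold -1.49 ± 0.51 SE, adjusted p = 0.117, or 0.000964 with the block) and Tnfrsf19 (-1.28 ± 0.49, adjusted p = 0.156, or 0.00308 with the block), both named after their values were seen. Cd44 was at 4295 ± 552 in duodenal and 2623 ± 397 in cecal tumors (log2 fold -0.71 ± 0.15 SE, adjusted p = 0.0215), a call lost without any single one of duodenal tumors 1 and 3 and cecal tumors 1 and 2 (adjusted p = 0.082, 0.0667, 0.0852 and 0.0873) and with the male arrays alone (0.0599). A second Cd44 probe set, at -0.69, did not pass (adjusted p = 0.0533). Sp5 had a log2 fold of -1.45 ± 0.40 (SE; adjusted p = 0.0602, or 0.00384 with the block and 0.0248 without duodenal tumor 1) and Sox9 one of -0.92 ± 0.25 (adjusted p = 0.0608, or 0.0101 with the block, 0.0411 without cecal tumor 3 and 0.0368 with the mean of its probe sets). A second Sox9 probe set, at -0.74, passed (adjusted p = 0.0275). The list's median was -0.69 (camera adjusted p = 0.00791; adjusted p = 0.754 with an estimated correlation). It did not pass without duodenal tumor 2 (adjusted p = 0.148), without cecal tumor 1 (0.105), with the male arrays alone (0.0639), with array weights (0.141) or by fry (0.32).

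Inflammation and antimicrobial genes were called higher in cecal tumors as a list. Of 15 tested members, Saa1, Saa2 and Saa3 rose and Reg1, a regenerating-family protein, fell, also adjusted over the list alone. For 3 of the 15, dim in all tumors of 1 site, the direction of the fold largely follows from the filter. Saa1 is also a member of the large intestine epithelium list, so those list calls share it. Saa3 rose from 321.7 ± 92.5 to 1110 ± 178 (log2 fold 1.76 ± 0.22 SE), and Reg1 was at least 32.9-fold higher in duodenal tumors. The list's median was 0.97 (camera adjusted p = 0.00292; adjusted p = 0.426 with an estimated correlation), and it did not pass under the filter at the 60th percentile (adjusted p = 0.0921). Of 12 interferon response genes, 3 rose, also adjusted over the list alone (list adjusted p = 0.109; 0.0491 without cecal tumor 2 and 0.0381 with the male arrays alone). Irf7, with the smallest p among them, had a log2 fold of 1.55 ± 0.24 (SE), a call lost with the male arrays alone (adjusted p = 0.0528). None of 5 MHC class II genes passed, also adjusted over the list alone (list adjusted p = 0.756).

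Fibroblast and matrix genes were called higher in cecal tumors. Of 17 members, 4 rose, or 11 adjusted over the list alone and 6 with the block. Vim, an intermediate filament of mesenchymal cells, rose from 1088 ± 30.1 to 2017 ± 375 (log2 fold 0.87 ± 0.15 SE), and the collagen gene Col3a1 from 4129 ± 695 to 6848 ± 830, a call lost without duodenal tumor 1 (adjusted p = 0.0646) or cecal tumor 1 (0.058) and with the male arrays alone (0.0902). The median was 0.43 (camera adjusted p = 4.79e-06; adjusted p = 0.375 with an estimated correlation). General epithelial genes were called higher too, with 3 of 13 rising, or 6 higher and 1 lower adjusted over the list alone and 5 and 1 with the block. Cldn3 rose by 1.20 ± 0.17 (SE) and Cldn7 by 0.50 ± 0.09, a call lost with the male arrays alone (adjusted p = 0.0868). The list's median was 0.24 (camera adjusted p = 0.00292; adjusted p = 0.375 with an estimated correlation).

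Few genes of other cell types passed. No member passed, also adjusted over the list alone, among 6 plasma cell genes (list adjusted p = 0.754), 6 mast cell genes (0.609), 11 smooth muscle genes (0.631) or 8 endothelial genes (0.838), and 1 of 15 macrophage genes did, Ctss, also adjusted over the list alone (list adjusted p = 0.0905). With the block 1 plasma cell gene fell. The call of Ctss was lost without duodenal tumor 1 (adjusted p = 0.055), cecal tumor 1 (0.0658) or cecal tumor 2 (0.0653) and with the male arrays alone (0.0587). Without duodenal tumor 2, the macrophage (adjusted p = 0.0138), mast cell (0.0344) and smooth muscle (0.0102) lists passed. With the male arrays alone the macrophage and smooth muscle lists passed (adjusted p = 0.0104 for each). The endothelial list's median was 0.07, its mean -0.00 and its test upward. Igha was at 12844 ± 2282 and 13361 ± 410, and Acta2 at 3929 ± 780 and 3731 ± 468, in duodenal and cecal tumors. Of 5 acinar pancreas genes, Cela1 fell by 1.56 ± 0.27 (SE; 1 gene higher and 2 lower adjusted over the list alone, 1 and 1 with the block; list adjusted p = 0.278). The 15 acinar genes on the array had a median intensity of 59.1 over the duodenal and 56.8 over the cecal arrays. Of these, 4 were above the 40th percentile on all duodenal and 3 on all cecal arrays, Zg16 among them at both sites. Zg16 was also the acinar list's gene counted as higher, and it is a member of the goblet cell list too. Its log2 fold was 2.79 (limma adjusted p = 0.117). It passed with the block (adjusted p = 0.0263), without duodenal tumor 2 (0.0219) and with the male arrays alone (0.0218). Lists with too few tested members for a test were those of B cells (2 of 3 rose, Blnk and Cxcl13), T and NK cells (1 of 3 rose, Thy1), enteric neurons and glia (S100b fell), adipocytes (0 of 3) and erythroid cells (0 members tested), with the same counts adjusted over each list alone. The call of Cxcl13 was lost without cecal tumor 2 (adjusted p = 0.0501) and with the male arrays alone (0.0898), and its second probe set, at 0.93, did not pass (adjusted p = 0.136). That of Thy1 was lost without any single array but duodenal tumor 1 (adjusted p = 0.0713 to 0.105), with no filter on dim probe sets (0.0579) and with the male arrays alone (0.184). Among sample handling genes, 3 of 14 immediate early and stress genes rose, or 5 higher and 2 lower adjusted over the list alone and 4 and 2 with the block (list adjusted p = 0.0758). That list passed without duodenal tumor 1 (adjusted p = 0.034) and without cecal tumor 1 (0.0127), and with no filter on dim probe sets (0.0381). None of 13 clock genes passed, also adjusted over the list alone (list adjusted p = 0.0762; 0.0488 with the block, 0.034 without duodenal tumor 1 and 0.0435 without cecal tumor 3).

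In all, camera called 9 of 32 tested lists, 6 higher and 3 lower in cecal tumors. With an estimated correlation 0 were called, and fry, which asks only whether a list's own genes move on balance, called 8. With the replicate number as a block 14 were called. Other splits of the 6 arrays into 3 and 3 gave up to 12 called lists with the same test and 0 called genes. Each of those splits mixes the sites within a group, so the 0 called genes are no check on false calls. Part of the site difference also remains between the groups of each such split, so the list counts are no rate of false calls.

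**Figure D2:**
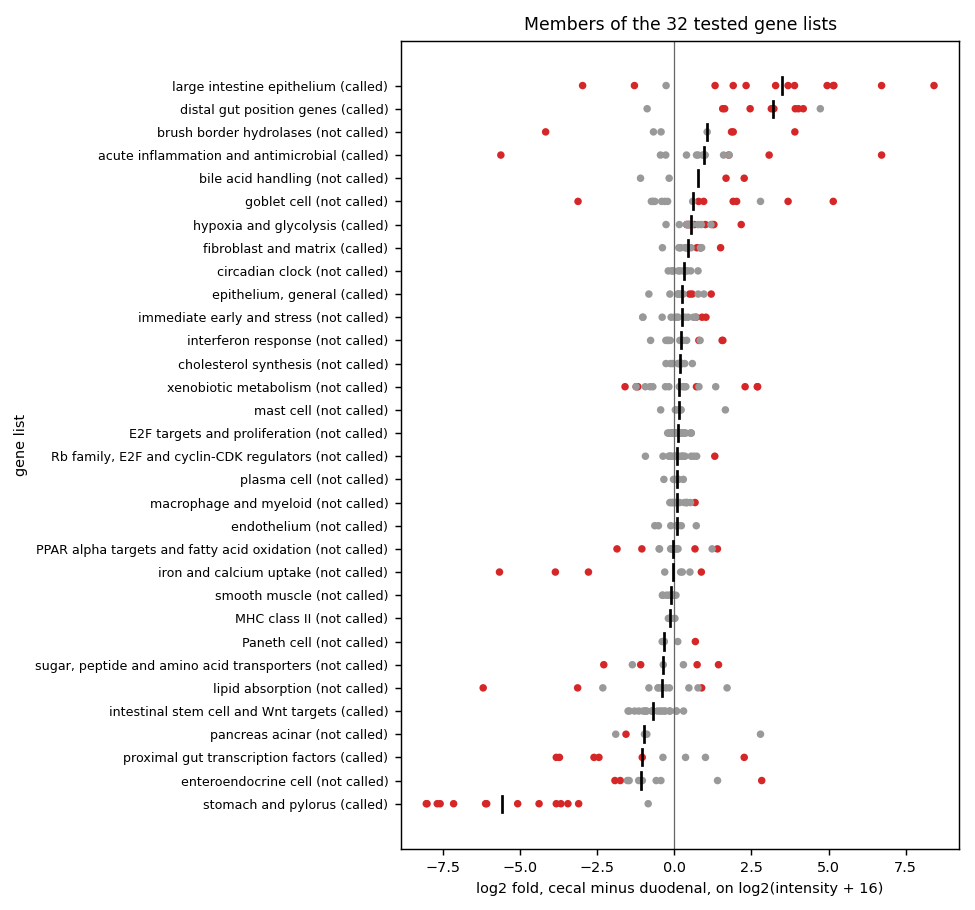
Log2 fold (cecal minus duodenal, on intensity + 16) of each tested member of the 32 tested gene lists, 1 line per list, ordered by the list's median (black bar). Red points are genes past the limma threshold of 0.05 and grey points are not; the stomach and pylorus list lies farthest to the left, at a median of -5.57, and large intestine epithelium farthest to the right, at 3.49.

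The arrays of both second tumors, 1 per site, showed the pattern of female mice and the others that of males, so sex was balanced. The brightest Xist probe set gave 4169.1 and 4486.3 in the second tumors and at most 61.6 in the others, and Eif2s3y, on the Y chromosome, 1.2 and 13 against at least 580.6. None of 3 tested sex-linked genes passed between the sites (adjusted p = 0.913 for Eif2s3y).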

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

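Of the alternatives here, the male-only fit and the count without the stomach list were chosen after the data were seen. Some of the 23 alternatives recomputed only the counts. Among the 202 named genes and 32 lists, no recomputed call was reversed. Over 202 named genes, 3344 of the recomputed calls were kept, 161 fell below the threshold and 67 rose above it; over the 32 lists the numbers were 552, 18 and 33. Leaving out 1 array gave 446 to 795 genes, 658 to 1194 probe sets and 9 to 14 lists, fewer arrays entering each fit. Probe sets fell to 816 and 856 without duodenal tumors 1 and 3, and to 658 and 700 without cecal tumors 1 and 2; lists rose to 14 without duodenal tumor 1 or 2. The male arrays alone (2 against 2) gave 695 probe sets, 490 genes and 14 lists. Array weights gave 1939 probe sets, an adjusted p under 0.01 gave 506 probe sets and 345 genes, and requiring a 2-fold difference as well gave 486 genes. An estimated correlation left 0 lists, with 9 under the preset one. The causes of the changed counts with array weights and the male arrays were not tested. The replicate block gave 1036 genes, 1571 probe sets and 14 lists and, beside the genes and lists for which its value is printed, changed no other call of a gene or list discussed in the text. The genes called with and without the block share 813. Without the stomach list 837 genes were called. Quantile normalization called 837 genes, 804 of them shared with the 850, and median centring 836, with 60% of calls higher in cecal tumors in place of 54.6%. Signal over background limits the folds: where a whole group lay under the 40th percentile only a bound can be given.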

Other observations

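The gene families and genes described here, and every test of an explanation, were chosen after the results were seen. Of 31 Hox genes on the array, 13 were tested. All 13 had a positive fold in cecal tumors, and 9 of them rose. A gene dim in every duodenal tumor was tested only if bright in every cecal tumor. The positive fold of such a gene largely follows from the filter. Hoxb3 was at least 2.65-fold and Hoxb5 at least 1.97-fold higher in cecal tumors, both genes of more anterior position than the listed ones. Water channels changed in both directions: Aqp8 and Aqp4 were higher in cecal tumors, while Aqp1, Aqp3 and Aqp5 were lower, all 5 tested having passed. The call of Aqp1 (adjusted p = 0.0296) was lost without duodenal tumor 1 (0.0937), duodenal tumor 3 (0.0954), cecal tumor 1 (0.0996) or cecal tumor 2 (0.088). Of 5 tested mucin genes, Muc3 and Muc13 rose and Muc1 and Muc5ac fell. The call of Muc13 (adjusted p = 0.0487) was lost with median centring (0.051), no filter on dim probe sets (0.0816), no intensity trend (0.0739) and without duodenal tumor 1 (0.0694) or any cecal tumor (0.0823 to 0.167). Of 10 tested steroid dehydrogenases 4 rose and 2, Hsd17b4 and Hsd17b11, fell, with Hsd11b2, which inactivates glucocorticoids, at a log2 fold of 3.02 ± 0.13 (SE, adjusted p = 9.8e-06) and Hsd17b2 at 1.35 ± 0.13. The call of Hsd17b4 (adjusted p = 0.0102) was lost without cecal tumor 2 (0.0505) and with the male arrays alone (0.0965), and its second probe set did not pass (0.0749). That of Hsd17b11 (0.0455) was lost with median centring (0.0685), no filter on dim probe sets (0.0752), no intensity trend (0.0721), the mean of its probe sets (0.0765) and without any single array but duodenal tumor 2 (0.0831 to 0.143), and its second probe set did not pass (0.23). Of 15 chemokine genes, Cxcl13, Ccl9 and Ccl28 rose and Ccl25, Ccl20 (lost with the male arrays alone, adjusted p = 0.0512) and Cxcl17 fell. Ccl25, a small intestinal chemokine, fell by 2.21 ± 0.18 on the log2 scale. None of 39 ribosomal protein genes passed the limma test. The secretory lectin gene Reg4 rose by 2.63 ± 0.28 and the amine oxidase Maoa by 4.17 ± 0.31.

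Duodenal tumor 2, the only duodenal tumor with the female pattern, stood apart from the other duodenal tumors. Hoxa9 was 2768.4 there, within the 2627.5 to 3662 of the cecal tumors, and Hoxa10 was 201.6 against 6 and 6.1 in the other duodenal tumors. The call of Hoxa10 (adjusted p = 0.0191) was lost without any single array but this one (0.0526 to 0.0753). Fabp1 was 683.8 there against 4236.3 and 4630.3, and Muc5ac 467.2 against 2430.2 and 4185.1. Gkn1, at 12495.9, lay beside the 12715.3 of duodenal tumor 1. A single tumor allows no test, and its sex cannot be told apart from its other traits.

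A hypothesis was that Hox genes of higher paralog number rise more. Across the 13 genes Spearman's rho of paralog number and log2 fold was 0.526 (permutation p = 0.0659 from 100000 resamples, two-sided; genes are not independent replicates). Most of these folds were against duodenal tumors under the 40th percentile and so are bounds, which leaves the ranks undetermined and the hypothesis untested.

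The stomach genes of the duodenal tumors may have more than 1 source. Carry-over of acid-secreting stomach body mucosa is argued against as the whole cause: Atp4a, Atp4b, Cblif and Chia1 had a median intensity of 50.9 over the duodenal arrays, where the 40th percentile averaged 100.4, although Cblif reached 256.1 and 364.5 in duodenal tumors 1 and 3 and Atp4a 135.7 in duodenal tumor 2. Pyloric tissue, which the labels allow in these samples, stays open. On 3 of 3 duodenal arrays 11 surface and antral stomach genes were above the 40th percentile. These genes are part of the pattern to be explained, so that count is no evidence for this source. In duodenal tumor 2, Gast (134.6) and Pgc (118.7) lay little above its level of 100.1. Gastric-type change of the tumor cells would raise the same genes. Pyloric tissue and such change cannot be told apart without the tumors' position or histology.

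For the higher glycolysis genes of cecal tumors, a lower share of epithelial cells stays open. The general epithelium list's mean log2 level was higher in cecal tumors by 0.321 ± 0.03 (SE, 3 tumors per site), against such a share. The fibroblast list's was higher by 0.521 ± 0.11, as a lower share would give, and the macrophage list's by 0.178 ± 0.08. The plasma cell (0.041 ± 0.14), mast cell (0.294 ± 0.77), smooth muscle (-0.142 ± 0.29) and endothelial (-0.004 ± 0.14) lists lay within their SE of no change. Over the mean of these other lists, macrophages included, the fibroblast list was higher by 0.448 ± 0.19. The 95% interval of that difference includes 0 and leaves out the pairing by number. This bar was set after the value was seen. Every earlier form had been read against a lower share: a camera p, the epithelium mean and a bar of 2 standard errors. A longer time without blood supply before freezing was not settled, since the immediate early and stress list did not pass (camera adjusted p = 0.0758). With the block 4 of its members rose and 2 fell, among them Hspa1b (log2 fold -1.01, limma adjusted p = 0.105, or 0.00363 with the block). No handling times were analysed here. A difference between cecal and duodenal tissue stays open and was not tested, and the list call itself is lost with an estimated correlation (adjusted p = 0.421).

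Tumors of the same replicate number deviated together, though they came from different mice. Genes on the sex chromosomes are argued against as the cause, since the lowest same-number correlation was 0.159 without them. Sex as the whole cause is argued against because male tumors of different numbers correlated at -0.093 on average and those of the same number at 0.238. A shared litter, day or array batch per number may be the cause and cannot be told apart: of the 6 ways to match the numbers, 1, the matching by number itself, had so high a mean correlation, and no label names a batch. Chance is not excluded either, since 1 of the 6 must be highest and matching the second tumors by sex leaves fewer ways. The -0.093 is partly set by deviations that cancel out within a site. Genes following the number included Defa31, at 2018.7 and 854.9 in the first tumors, 6268.5 and 5083.8 in the second and 28.1 and 40.6 in the third (duodenal and cecal), and Tmem87a, at 15.9 and 37.9 in the first tumors and at least 395.7 in the others.

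The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1290 probe sets and 850 genes, and the highest other split 0 of either, so 1 of the 10 splits gave as many. Every other split mixes the sites within a group, which puts the site difference into the spread within groups. Its 0 is therefore no check on false calls. For lists the real split gave 9 and the highest other 12, and 7 of the 10 splits gave at least 9. Among splits that part all 3 same-number pairs, as the real one does, the others gave 9, 11 and 6 lists, and 0 genes. Part of the site difference remains between the groups of every other split. The list counts of those splits are therefore no rate of false calls, and they neither back nor weaken the 9 calls. At an unadjusted limma p under 0.05 the real split gave 3229 probe sets and the others 180 to 687, where the same mixing of sites applies.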
